A study of Homo sapiens with 3 samples.

How the data were processed

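Lactylation of histone H4 at lysine 12 (H4K12la) was mapped by CUT&Tag, in which an antibody directs a transposase fused to protein A to chromatin carrying the mark, and the tagged DNA is amplified and sequenced. Per the labels' protocols, untreated 786-O and Caki-1 cells were bound to concanavalin A beads, incubated with an antibody against the mark and a secondary antibody, and tagmented, and the libraries were sequenced as paired ends on an Illumina NovaSeq instrument. The labels give the cell line and the replicate number of each library. 3 libraries were used, 1 of 786-O (replicate 2) and 2 of Caki-1 (replicates 1 and 2), and replicate 1 of 786-O was not analysed here. The labels do not say that the Caki-1 replicates came from separate cultures, so the spread between them may be technical.

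The submitters' processing notes name fastp 0.19.6, Bowtie2 and deepTools and the builds hg38 and GRCh38, with no roles. The peak caller, its threshold, any control library and the read depth are not given in the sources used here. Each library has its own deposited list of peaks without a header, so peaks were called per library and not on pooled reads. Each line holds a chromosome, a first and last base counted from 1, a width in bp and 2 further columns. The width equals the last base minus the first plus 1 in 100% of the lines of each list.

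The meaning of the last columns was read from the values. In the lists of 786-O and of Caki-1 replicate 1, column 5 lies inside the peak in 100% of lines and was taken as its summit. Column 6 of these lists holds whole numbers, and it was read as the deposited signal at the summit, a pileup of fragments that no source describes as scaled to depth. In the list of Caki-1 replicate 2, column 5 lies inside the peak in only 9.65% of lines, and 30.0% of its distinct positions lie within 20 bp of the lower coordinate of an annotated gene, so it was not used as a summit. Column 6 of that list is read here as a deposited score, with a lowest value of 13, which is what 10 times the negative log10 of q gives at a q of 0.05. Column 6 is the authors' value per peak and was used only to describe, rank or filter peaks within a list, as a percentile rank with ties at their mean. The values given per gene are each list's own, not scaled to depth, and are not compared between libraries. Ratios of signal were formed only between 786-O and Caki-1 replicate 1, by chromosome or 10 Mb bin and after centring on the median log2 ratio over all shared peaks.

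Gene positions came from a table of 59792 RefSeq genes on GRCh38.p14, the build that the submitters' notes name. It gives both ends of each gene model and no strand, and no genome sequence was used here. The design had fixed windows around transcription start sites and strength as fold enrichment. These were replaced by a window of 1 kb on each side of either annotated end of a protein-coding gene, and by the rank of column 6. A gene-end peak may therefore lie at a promoter or at the far end of a gene. Peaks were classed as within 1 kb of a gene end, elsewhere within a gene extended by 1 kb, or outside genes. All 3 lists cover chromosomes 1 to 22 and X, which hold 19974 protein-coding genes.

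The share of gene-end peaks was set against 1000 random placements of the same peaks on the same chromosome, a one-sided permutation of positions. Chromosome lengths were taken as the highest coordinate of a gene or peak, and gaps in the assembly were not left out. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only, and differences of medians carry 95% intervals from 500 bootstrap resamples. The median rank at genes specific to Caki-1 carries a 95% order-statistic interval, used in place of a bootstrap because ties let the lower bound of the bootstrap fall on either side of 50 with the seed. Peaks were counted as shared at an overlap of at least 1 bp, with chance taken from the same kind of placement. With 3 libraries there are 3 possible labelings, so the smallest p between the lines is 0.333 and no such test was made.

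A gene counted as specific to a line when it had a gene-end peak there and no peak within 5 kb of either end in the other line. 19 gene lists were fixed before the data were examined, with 355 members, of which 351 are distinct. 1 member was matched through an older symbol (NDUFA4, now COXFA4). The number of members with a gene-end peak was given as a percentile among 10000 random lists of the same size from all protein-coding genes. Ties were split evenly. A list is called above or below the random lists outside the range from 2.5 to 97.5. No p-value was computed across genes. Correlations across the 23 chromosomes used 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over 3 relations.

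The genes named in the text follow a rule fixed before the data were examined. It takes the 10 genes with the highest value of their lowest rank over the 3 libraries, and the 10 highest-ranked genes specific to each line. It adds up to 4 members of each list with the highest lowest rank, up to 4 members in alphabetical order with no gene-end peak or with one in a single line, and the 3 widest peaks of each library. Where a peak lies at the ends of several genes this is said, and histones and near-identical copies are given as uncertain. Some genes that the rule takes are not reported here. Other members of the lists are named where the text says how many of a list had a peak.

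The alternatives tried were the stronger 50% of each list, the 60760 strongest peaks of each list, windows of 500 bp and 3 kb, and a reciprocal overlap of 50%. Further ones were merging of peaks within 500 bp, no guard distance, random placement over all chromosomes and leaving out each Caki-1 library. Alternatives added after the data were seen were placement within 50 kb of each peak, random lists matched on gene length or on gene density in 10 bins each, and leaving out 6 chromosomes. The counting steps were tested on simulated lists of 62777 peaks: 100% of planted gene-end peaks and 100% of planted shared peaks were found, and 0% were wrongly called shared. The planted peaks met the definitions by construction, so this checks the counting and not the peak calls. Of 400 random lists of 20 genes, 94.5% fell inside the range from 2.5 to 97.5. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.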

Results

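H4K12la was profiled by CUT&Tag in untreated cells of 2 established human renal carcinoma lines, 786-O, which lacks functional VHL, and Caki-1, which retains it. The series set out to find genes that carry the mark in clear cell renal cell carcinoma. The list of 786-O replicate 2 held 62777 peaks covering 36.4 Mb, and those of Caki-1 replicates 1 and 2 held 60760 and 67839 peaks covering 36.5 and 45.2 Mb. Median peak widths were 497, 520 and 576 bp in the same order. The read depth behind the lists is not given in the sources used here, so differences in peak number between libraries cannot be separated from depth. All coordinates are on GRCh38. 786-O has no replicate here, and no value of that line carries a replicate error.

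The first question was where the mark lies relative to genes. The highest-ranked peaks at gene ends in all 3 libraries lay at housekeeping genes of DNA replication, trafficking and nucleotide supply. The top one, on chromosome 16 from 46688658 to 46690179 in 786-O, spanned the lower end of ORC6, a subunit of the origin recognition complex, and the higher end of VPS35, a retromer subunit, and both genes share it. Its summit signal was 164 in 786-O and 164 in Caki-1 replicate 1, and its score was 1051 in Caki-1 replicate 2, against list medians of 21, 21 and 48. RRM2B, a subunit of ribonucleotide reductase, followed with signals of 188 and 147 and a score of 682 at its higher end on chromosome 8 (102238653 to 102239731 in 786-O). RAB1A, a GTPase of transport from the endoplasmic reticulum to the Golgi, had signals of 196 and 136 and a score of 614 at its higher end on chromosome 2 (65129668 to 65131071).

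Other genes of this group were CACYBP on chromosome 1, the pair ARID4B and GGPS1 on chromosome 1, and the pair DCAF13 and SLC25A32 on chromosome 8. Each pair shared a single peak between neighbouring gene ends. CACYBP had signals of 173 and 206 in 786-O and Caki-1 replicate 1, the ARID4B and GGPS1 peak 141 and 133, and the DCAF13 and SLC25A32 peak 144 and 119. All of these genes ranked at the 99.9 percentile or higher in each list.

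Gene ends held far more peaks than random placement gives. In 786-O, 15.9% of peaks (95% CI 15.6 to 16.2) lay within 1 kb of either end of a protein-coding gene, against 3.17% in random placements on the same chromosome, a ratio of 5.0. The shares were 17.2% (16.9 to 17.5) and 16.2% (16.0 to 16.5) in Caki-1 replicates 1 and 2, with ratios of 5.44 and 5.0. No placement reached these shares, and the one-sided permutation p was 0.001 in each library, the smallest that 1000 placements give. Against placement within 50 kb of each peak, which keeps the local gene density, the ratios were 3.03, 3.23 and 2.97. A further 53.5%, 53.7% and 54.7% of peaks lay elsewhere in genes, and 30.7%, 29.1% and 29.0% outside them.

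Peaks at gene ends were stronger and wider than the others in each library. Their median summit signal was 38 against 20 in 786-O and 33 against 19 in Caki-1 replicate 1, and their median score was 101 against 43 in Caki-1 replicate 2. Their median widths exceeded those of other peaks by 224 bp (95% CI 215 to 232), 226 bp (217 to 234) and 269 bp (258 to 278). The widest peak of all 3 libraries lay on chromosome 21 in LOC105377134, with LIPI as the nearest protein-coding gene, and measured 3514 bp in 786-O (14055772 to 14059285). A second wide peak on chromosome 21, in LOC102724701, measured 3435, 3413 and 3401 bp. BRD2, which encodes a bromodomain reader of acetylated histones, held the third widest peak of 786-O on chromosome 6 (32968308 to 32971223, 2916 bp). In Caki-1 replicate 1 the third lay 4537 bp from ANKRD62 on chromosome 18 (12086477 to 12089306), and in replicate 2 the second lay within TSHZ1 on chromosome 18 (75247011 to 75250650).

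The second question was how far the peaks of the lines differ, set against the difference between the Caki-1 replicates. Peaks at gene ends were mostly common to both lines, and sharing was lower away from gene ends. Since gene-end peaks were also stronger and wider, and position was not compared at equal strength, the 2 cannot be separated here. Of the gene-end peaks of 786-O, 80.2% and 82.6% overlapped a peak of Caki-1 replicates 1 and 2, and 76.3% and 74.3% of those of the replicates overlapped 786-O, against 88.8% and 83.9% between the Caki-1 replicates in either direction. Outside genes, 34.2% and 36.7% of the 786-O peaks were shared with Caki-1, against 61.8% and 55.0% between the replicates. Within genes but away from their ends the values were 39.8% and 43.8% for 786-O against 61.3% and 53.4% for the replicates.

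**Figure D1:**
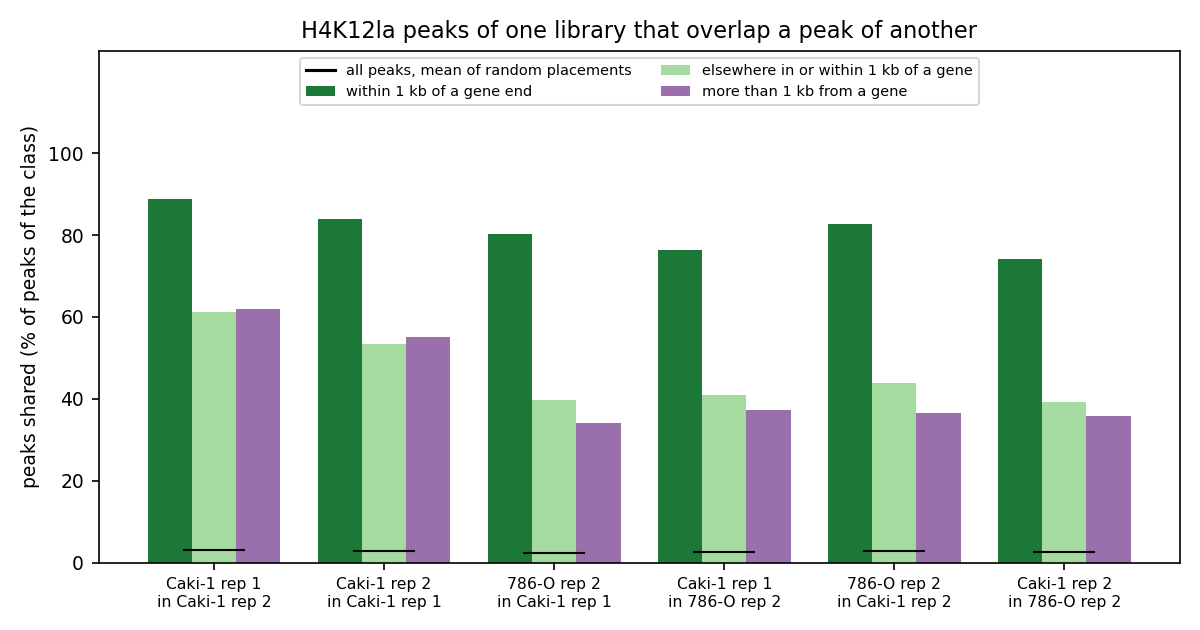
Percentage of peaks of a library (first line of each label) that overlap a peak of another (second line) by at least 1 bp, by position relative to protein-coding genes; black lines give the mean of 1000 random placements for all peaks. Gene-end peaks were shared at 74.3% to 88.8% in the 6 comparisons, and peaks outside genes at 34.2% to 37.2% between lines and 55.0% to 61.8% between replicates.

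Over all peaks, 66.2% of Caki-1 replicate 1 (95% CI 65.8 to 66.5) overlapped replicate 2, and 58.8% (58.5 to 59.2) the reverse. Between the lines, 44.5% and 47.8% of 786-O peaks overlapped Caki-1 replicates 1 and 2, and 46.0% and 43.9% of the peaks of those replicates overlapped 786-O. Random placements gave 2.48% to 3.13%, with a permutation p of 0.001 for each of the 6 comparisons, the smallest possible. The Jaccard index by base was 38.9% between the replicates and 25.2% and 25.3% between 786-O and either of them, a difference of 13.6 percentage points. Of 116359 regions in the union of the lists, 23806 (20.5%) were covered in all 3 libraries and 28491 (24.5%) in 786-O alone. Caki-1 replicate 1 alone covered 16277, replicate 2 alone 21753, and both Caki-1 libraries without 786-O 16007 (13.8%). The last count asks for presence in 2 libraries and that of 786-O for presence in 1. 786-O also has no replicate here that could share its regions, so the counts of the lines are not symmetric. The strongest 10% of each list was shared at 86.6% to 90.7% between lines and 97.8% and 99.1% between replicates, and the weakest 10% at 12.6% to 18.9% and 26.3% and 18.9%. With 1 library of 786-O the difference between lines could not be tested.

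The third question was which genes carry the mark. Of 19974 protein-coding genes, 10530 (52.7%) had a gene-end peak in 786-O, and 11004 (55.1%) and 11513 (57.6%) in Caki-1 replicates 1 and 2. 8858 genes (44.3%) had one in all 3 libraries and 6917 (34.6%) in none. About 90% of them had it at a single end, with 9435 of the 10530 in 786-O. Genes with a peak in 786-O and none within 5 kb in either Caki-1 library numbered 473, and 864 genes had peaks in both Caki-1 libraries and none within 5 kb in 786-O. These counts are not symmetric, since the first asks for absence from 2 libraries and the second for presence in 2.

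Among the genes specific to 786-O, the highest-ranked was SEMA5A, which encodes a semaphorin of axon guidance, with a peak of 2043 bp and a signal of 82 at its higher end on chromosome 5 (9545855 to 9547897). EFNB1, which encodes the membrane-bound ligand ephrin B1, had a signal of 73 at its lower end on chromosome X (68828625 to 68829269). ZBTB1 and ZBTB25, zinc finger genes that share a peak on chromosome 14 (64503374 to 64504789), had a signal of 61. SLC25A1, the mitochondrial citrate carrier, had 59 on chromosome 22 (19178815 to 19179659), and the casein kinase gene CSNK1E on the same chromosome had 48. RBM15B on chromosome 3, COPE on chromosome 19 and LOC124900275 on chromosome 9 had signals of 52, 49 and 49. TVP23B on chromosome 17 had 72, but it has a near-identical copy, TVP23C, and this value is uncertain.

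Among the genes specific to Caki-1, SPMAP2L on chromosome 4 (56530286 to 56530999 in replicate 1) ranked highest, with a signal of 82 in replicate 1 and a score of 401 in replicate 2. BHMT2 and DMGDH, which encode metabolic enzymes, share a peak of 1575 bp on chromosome 5 (79069290 to 79070864) with a signal of 66 and a score of 266. The nucleoporin gene NUP133 on chromosome 1 had 69 and 265, TMEM94 on chromosome 17 had 69 and 263, and GNPTAB, whose product builds the mannose 6-phosphate tag of lysosomal enzymes, had 65 and 256 on chromosome 12. BANK1, an adaptor of B cell receptor signalling, had 63 and 464 on chromosome 4. ANKRD35 on chromosome 1, PCBP3 on chromosome 21 and CCDC92 on chromosome 12 had signals of 64, 72 and 63 and scores of 357, 253 and 265.

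From the same Caki-1 library, more genes lacked a peak in 786-O than in the other replicate. 880 genes of 786-O (8.36%) had no peak within 5 kb in Caki-1 replicate 1, and 695 (6.60%) had none in replicate 2. In the other direction, 1103 (10%) and 1264 genes (11.0%) of replicates 1 and 2 had none in 786-O. Between the replicates the numbers were 410 (3.73%) and 722 (6.27%), the second close to the 695 of 786-O. With no guard distance 1117 of the 10530 genes of 786-O were absent from replicate 2, and 1250 of the 11513 genes of replicate 2 from replicate 1. The count of 473 depends on the settings: it was 880 without Caki-1 replicate 2, 695 without replicate 1, 803 with no guard distance and 851 with a window of 3 kb. The count of 864 rose to 1405 with no guard distance, 1264 without Caki-1 replicate 1, 1103 without replicate 2 and 1165 with a window of 3 kb.

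The 19 gene lists showed which groups carried the mark at their ends in all 3 libraries. 7 lists lay above the random lists, 5 below and the rest inside their range, with no allowance for the number of lists. Presence and absence in the lists were judged by gene-end peaks alone. Of the list members named as having one in a single line or library, only PFKL, IER2, WT1 and KDR in 786-O and E2F1, CA12, KAT2A, LLGL2, OCLN, FGFR2, TNNT2 and NDUFV1 in Caki-1 had no peak within 5 kb in the other line. Values are those of the highest-ranked gene-end peak of each library, which was not the same peak in each for E2F1, ERBB3, IL6, MYC and CSF1R. The cell cycle list had 20 of 22 genes against a median of 10 in random lists (percentile 100). AURKA, a mitotic kinase, had signals of 80 and 122 and a score of 289. The replication helicase subunit gene MCM4 had 118, 80 and 225, and the cyclin genes CCNE2 and CCNB2 had 80, 49 and 225, and 62, 49 and 182. E2F1, a transcription factor of S phase entry, had no peak in 786-O and a signal of 43 and a score of 90 in Caki-1.

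Oxidative phosphorylation had 23 of 25 genes (percentile 100), the highest share of all lists. COXFA4 had signals of 115 and 114 and a score of 604, ATP5F1C, a subunit of ATP synthase, had 87, 98 and 464, SDHA, the flavoprotein of succinate dehydrogenase, had 103, 84 and 303, and UQCRB had 76, 86 and 299. NDUFV1 had a gene-end peak in Caki-1 replicate 2 alone. Cytosolic ribosomal proteins had 20 of 25 genes (percentile 100), led by RPL7 with 139, 107 and 326, RPS6 with 73, 53 and 189 and RPL5 with 85, 40 and 201. RPS2 had none, RPL11 had a peak in both Caki-1 libraries only and RPL18 in 786-O only.

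Of the tumour suppressors of clear cell carcinoma and the mTOR pathway, 14 of 16 genes had a gene-end peak in all 3 libraries (percentile 99.97). These included VHL, PBRM1, BAP1 and SETD2, and the highest ranks belonged to MTOR, with signals of 61 and 46 and a score of 161, and to RHEB, its GTPase activator, with 77, 57 and 138. PIK3CA had 74, 45 and 138, RICTOR had 74, 43 and 132, and ARID1A had a peak in Caki-1 replicate 2 alone. Genes that write, erase or read histone acylation had 16 of 21 (percentile 99.9). AARS1, an alanyl-tRNA synthetase reported to transfer lactate to proteins, had signals of 82 and 97 and a score of 329 on chromosome 16 (70288704 to 70289681 in 786-O). HDAC6 had 69, 59 and 267, KAT8 had 52, 46 and 195, and KAT7 had 49, 44 and 159. AARS2 had no gene-end peak, the acetyltransferase genes CREBBP and KAT2A had one in Caki-1 only, and KAT2B had one in 786-O only.

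The hypoxia response had 15 of 22 genes in all 3 libraries (percentile 98.7), among them HIF1A and EPAS1, the subunits that VHL targets for degradation. HILPDA, an inhibitor of lipolysis, had signals of 55 and 53 and a score of 230. The prolyl hydroxylase genes P4HA1 and P4HA2 had 53, 57 and 169, and 54, 53 and 149, and the mitophagy receptor gene BNIP3L had 58, 44 and 154. CA9 and EPO had no gene-end peak and CA12 had one in Caki-1 only, with a signal of 18 and a score of 59. This percentile fell inside the random range with a window of 3 kb (93.6) and against lists matched on gene density (97.1). Lipid and sterol genes had 13 of 18 (percentile 99.0, and 97.4 against lists matched on gene length). SQLE and HMGCS1, enzymes of cholesterol synthesis, had signals of 85 and 89, and 90 and 55. ACACA had 48 and 65, CPT1A had no gene-end peak, and ELOVL6 and PNPLA2 had one in a single Caki-1 library.

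**Figure D2:**
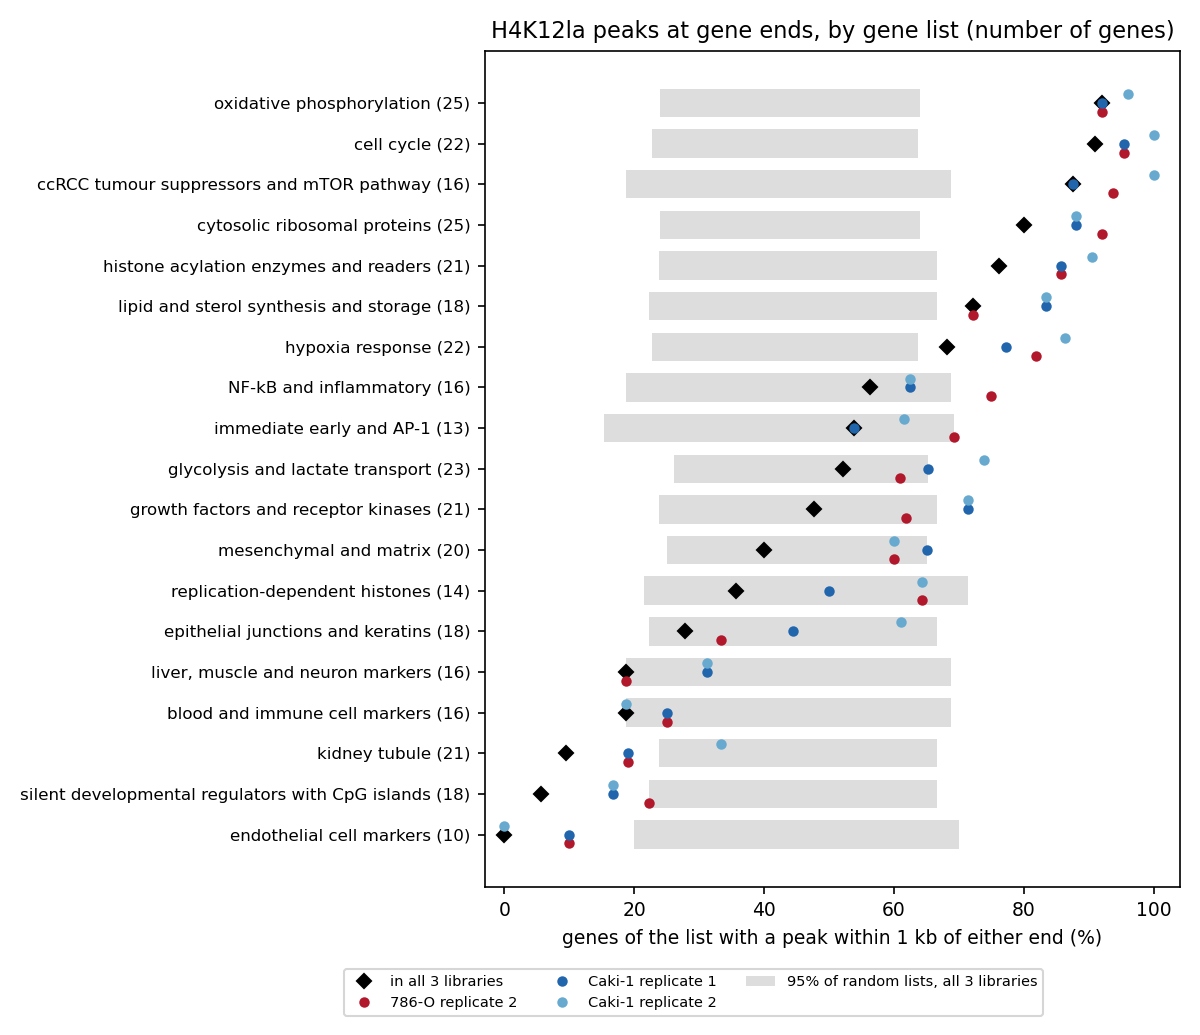
Percentage of the genes of each list with an H4K12la peak within 1 kb of either end, per library (circles) and in all 3 libraries (diamonds); grey bars span the central 95% of 10000 random lists of the same size for the count in all 3 libraries and apply to the diamonds only. Diamonds lie above the bars for 7 lists, up to 92.0% of the genes of oxidative phosphorylation, and below or at their lower edge for 5, down to 0% of the endothelial markers.

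Glycolysis and lactate transport, the pathway that supplies lactate, lay inside the random range, with 12 of 23 genes in all 3 libraries against a median of 10 (percentile 77.2, from 43.2 to 99.4 over the alternatives, the last with a window of 3 kb). LDHA, LDHB, GAPDH and the lactate carriers SLC16A1 and SLC16A3 were among the 12. PDK1 had signals of 42 and 46 and a score of 159, PFKM had 41, 45 and 210, and PGK1 had 33, 39 and 232. GPI and ENO1 had gene-end peaks in both Caki-1 libraries and not in 786-O, where a peak lay within 5 kb of each. PFKL had one in 786-O only (signal 29, chromosome 21, 44300493 to 44300886), and HK1, PFKP, PFKFB3, ALDOC and TPI1 had none.

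5 more lists concern cell state and signalling, and all of them also lay inside the random range in all 3 libraries. The epithelial list had 5 of 18 genes (percentile 8.02, from 0.36 with a window of 500 bp to 27.0 over the alternatives). KRT8 and KRT18 share a peak with signals of 30 and 29 and a score of 99, CLDN1 had 35, 29 and 65, and CDH1 and CRB3 had no gene-end peak. Per library, 6 epithelial genes had a peak in 786-O against 8 and 11 in Caki-1, where LLGL2 and OCLN had peaks and 786-O had none within 5 kb. The mesenchymal list had 8 of 20 (percentile 35.3), with SPARC at signals of 62 and 56 and a score of 236 and FN1 at 36, 32 and 100. AXL had a gene-end peak in Caki-1 only (39 and 131) and ZEB2 in 786-O only (38), each with a peak within 5 kb in the other line, and CCN1 and COL3A1 had none. Growth factors and receptors had 10 of 21 (percentile 62.2), with MET at 53, 50 and 112 and TGFA at 46, 37 and 122. ERBB3 had 59, 37 and 105, FGFR2 and HBEGF had gene-end peaks in Caki-1 only, HBEGF with a peak within 5 kb in 786-O, and FGFR1 had no gene-end peak.

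NF-kB and inflammatory genes had 9 of 16 (percentile 82.1), with 12 in 786-O against 10 and 10 in Caki-1. RELB had signals of 64 and 65 and a score of 308, NFKB1 had 44, 30 and 82, and IL6 had 43, 29 and 89. BIRC3 had a gene-end peak in 786-O only (49) and a peak within 5 kb in Caki-1, and CCL2, CXCL8 and IL1B had none. Immediate early genes had 7 of 13 (percentile 75), with EGR1 at 47, 48 and 157 and MYC at 46, 49 and 98. FOSL2 and IER2 had gene-end peaks in 786-O only and ATF3 in Caki-1 replicate 2 alone, and FOSL2 and ATF3 had a peak within 5 kb in the other libraries. Replication-dependent histones had 5 of 14 (percentile 26.9, from 0.08 in the stronger 50% of peaks to 85.3 against lists matched on gene length), but their copies are near-identical and these values are uncertain. Of all 74 replication-dependent histone genes, a set formed after the data were seen, 24 had a peak in all 3 libraries. That percentile of 2.13 lay just below the random range. In 786-O and Caki-1 replicates 1 and 2, 39, 36 and 42 of the 74 had a peak, from 27, 24 and 29 distinct peaks. Some of these genes therefore share a peak and do not count independently. H2BC5 had signals of 28 and 17 and a score of 42, and H2BC12 had 31, 16 and 55.

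The lists below the random range were those of developmental regulators and of other cell types, and also the kidney tubule list. Only 2 of 21 tubule genes had a peak in all 3 libraries (percentile 0.035), among them CDH16 with signals of 27 and 41 and a score of 82. PAX8, a lineage factor of the renal epithelium, had a signal of 53 and a score of 140 in Caki-1 on chromosome 2 (113278439 to 113279710 in replicate 1) and no gene-end peak in 786-O. LRP2 had a peak in Caki-1 replicate 2 alone, AQP2 in 786-O alone, and AQP1 and CUBN had none. Of the developmental regulators, 1 of 18 had a peak in all 3 (percentile 0.02). PAX6 and WT1 had peaks in 786-O only, with 24 and 27, and SOX17 in Caki-1 only, while DLX5, GATA4 and LHX2 had none.

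None of the 10 endothelial markers had a peak in all 3 libraries (percentile 0.12). KDR had one in 786-O only, with a signal of 23, and CDH5 in Caki-1 replicate 1 alone, with 18. The liver, muscle and neuron list had 3 of 16 (percentile 1.94, and 3.70 with a window of 500 bp), SERPINA1, APOA1 and SNAP25. SERPINA1 had signals of 28 and 35 and a score of 54, and TNNT2 had 56 and 191 in Caki-1 and no peak in 786-O. Blood and immune markers had 3 of 16 (percentile 1.98), CSF1R with 36, 31 and 54, CD8A with 21, 18 and 78, and CD14 with 14, 22 and 82. That percentile lay between 0.345 and 5.59 over the alternatives, and CD3D, CD3E and CD79A had no gene-end peak.

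Chromosomes also differed between the lines in their share of peaks. As a share of all peaks, chromosomes 14, 6 and 22 held 2.19, 2.02 and 1.90 times as many peaks in 786-O as the mean of the Caki-1 libraries, and chromosomes 13, 17 and 2 held 0.452, 0.789 and 0.807 times as many. On chromosome 14 the numbers were 2294 in 786-O against 1002 and 1143 in Caki-1, and on chromosome 13 they were 766 against 1611 and 1866. The SD of the log2 ratio over the 23 chromosomes was 0.49 between the lines and 0.03 between the Caki-1 replicates. Chromosomes 14, 6 and 22, where ZBTB1, ZBTB25, SLC25A1 and CSNK1E lie, hold 10.5% of the genes but 98 of the 473 genes specific to 786-O (20.7%) and 53 of the 864 specific to Caki-1 (6.13%). Chromosomes 13, 17 and 2 hold 13.8% of the genes, 37 (7.82%) of those specific to 786-O and 159 (18.4%) of those specific to Caki-1. Of the highest-ranked genes specific to a line, TMEM94 of Caki-1 and TVP23B of 786-O lie on chromosome 17, which was not uniform. The log2 ratio of summit signal of 786-O to Caki-1 replicate 1 was -0.78 at 70 to 80 Mb, where TMEM94 lies. It was 0.35 at 10 to 20 Mb, where TVP23B lies, so that part was not poorer in 786-O. Without these 6 chromosomes 338 and 652 genes were left. Parts of the remaining chromosomes also differed, as given below, so these counts are not free of such differences. Several of the highest-ranked genes specific to a line lie in such parts.

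**Figure D3:**
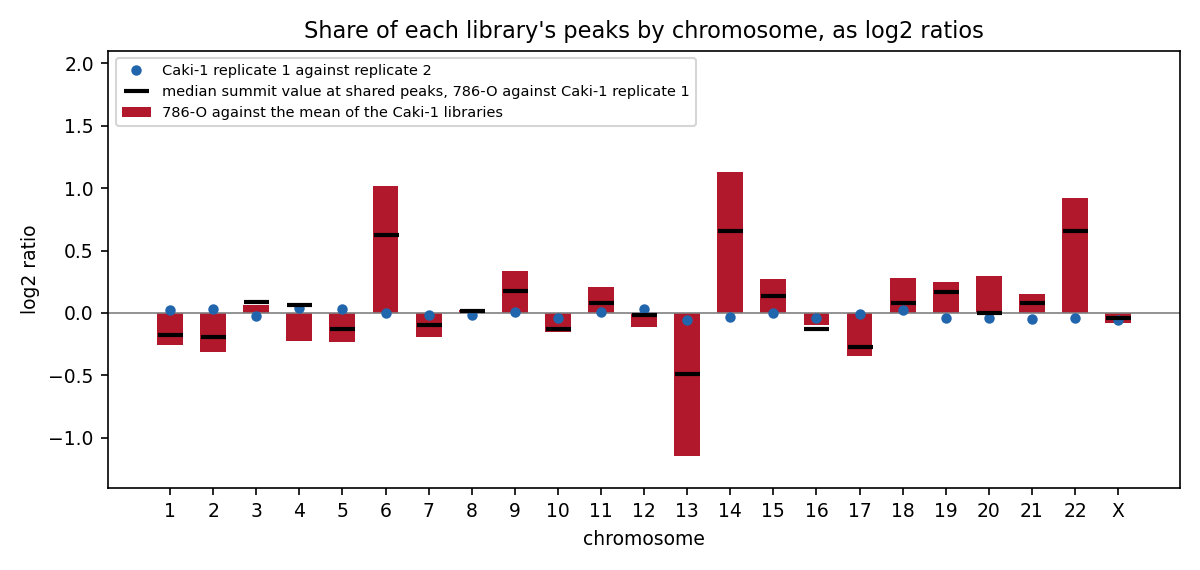
Log2 ratio, per chromosome, of the share of peaks in 786-O to the mean share in the Caki-1 libraries (bars) and of Caki-1 replicate 1 to replicate 2 (circles), with the median log2 ratio of summit signal at peaks shared by 786-O and Caki-1 replicate 1, centred on all shared peaks (dashes). The bars run from -1.15 on chromosome 13 to 1.13 on chromosome 14, and the circles stay between -0.05 and 0.04.

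Summit signal at shared peaks was highest on the same 3 chromosomes and lowest on chromosome 13. Relative to all shared peaks, its median log2 ratio of 786-O to Caki-1 replicate 1 was 0.66 on chromosome 14, 0.65 on chromosome 22 and 0.62 on chromosome 6, and -0.49 on chromosome 13. Across the 23 chromosomes, which are not independent replicates, it correlated with the ratio of peak shares at Pearson r = 0.959 and Spearman rho = 0.912 (permutation p = 1e-05 for both, the smallest that 100000 permutations give, adjusted p = 2e-05 over 3 relations). Without chromosomes 13 and 14, the farthest from the median, r was 0.947. The ratio of line-specific genes followed the ratio of peak shares with r = 0.769 (permutation p = 4e-05, adjusted 4e-05) and rho = 0.759 (p = 2e-05, adjusted 2e-05), and r was 0.761 without the same chromosomes. Both of these ratios were formed from the same peak lists, so they are not independent measures. The ratio of peak shares at gene ends followed that outside genes with r = 0.907 (permutation p = 1e-05, adjusted 2e-05) and rho = 0.864 (p = 2e-05, adjusted 2e-05), and r was 0.879 without chromosomes 22 and 6. The ratio at gene ends was smaller, 0.25 on chromosome 14 on the log2 scale against 1.61 outside genes.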

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

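The test of repeated and mitochondrial DNA in this part was chosen after the strongest peaks had been seen.

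The strongest peak of each list lay over mitochondrial pseudogenes and not at the genes the comparisons were about, which is a signal outside the main measurement. The pseudogenes MTND1P23, MTND2P28, MTCO1P12, MTCO2P12, MTATP8P1, MTATP6P1 and MTCO3P12 lie side by side on chromosome 1, where peaks of 786-O ran from 629228 to 634596. The highest summit signal there was 1335 in 786-O and 3742 in Caki-1 replicate 1, which is 63.6 and 178 times the median of each list, and the highest score in Caki-1 replicate 2 was 5677. The next strongest peak of Caki-1 outside that stretch lay over MTND4P12 inside PCBD2 on chromosome 5 (134926819 to 134927357), with a signal of 671 in replicate 1 and a score of 3870 in replicate 2. No control library without the antibody was used here, so the background at these places is unknown.

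A candidate explanation is that reads of mitochondrial DNA, or of ribosomal DNA with many copies, align to these near-identical stretches. Of the 10 strongest peaks, 3 in 786-O, 3 in Caki-1 replicate 1 and 4 in replicate 2 lay within 10 kb of an annotated mitochondrial pseudogene or ribosomal RNA gene, against 0.505%, 0.487% and 0.503% of all peaks. The lowest of these numbers, 3, does not decide whether reads of repeated or mitochondrial DNA are the cause, since the test was set after these peaks had been seen and the 3 peaks of 786-O lie in 1 stretch of chromosome 1. Peaks on chromosome 21 near 8234103 and on chromosome 17 near 26603692, also among the strongest in all 3 lists, had no such gene within 10 kb. Nor did the wide peak in LOC102724701 on chromosome 21, among the 10 strongest of 786-O and Caki-1 replicate 1 with signals of 250 and 226. In Caki-1 replicate 2 another of the strongest peaks on chromosome 21 (8219527 to 8220435) had the ribosomal RNA gene RNA45SN2 within 10 kb. A fixed distance of 10 kb may therefore miss repeated DNA, and these peaks do not speak against that explanation. Lactylated histones at the pseudogenes themselves were not tested and remain open.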

How the results depend on the processing

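Placement within 50 kb, lists matched on gene length or gene density, and leaving out 6 chromosomes were chosen after the data were seen, and the other alternatives before. Of the values that answer a comparison, 76 stayed the same under an alternative and 64 moved by more than their interval, the spread between replicates or, for counts of genes, 1.5 times. No single value changed its sign. The ratios to random placement were judged by direction and permutation p alone, and they count as the same although placement within 50 kb lowered them to 3.03, 3.23 and 2.97. Percentiles of single gene lists kept their side of the random range in 141 cases, moved inside it in 8 and moved out of it in 3. Libraries are given below in the order 786-O, Caki-1 replicate 1, Caki-1 replicate 2.

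The share of gene-end peaks was 25.5%, 26.8% and 25.4% in the stronger 50% of each list, 13.9%, 15.3% and 14.5% with a window of 500 bp, and 21%, 21.8% and 21% with 3 kb. With the same number of peaks it was 16.3% in 786-O and 17.5% in Caki-1 replicate 2. The window shifts follow from its size. The difference in median percentile rank between gene-end and other peaks was 29.6, 28.1 and 29.9 in the stronger 50%, 40.2, 34.5 and 38.5 with 500 bp, and 32.0, 32.0 and 29.3 with 3 kb. With the same number of peaks it was 39.5 in 786-O and 35.3 in Caki-1 replicate 2. The difference in median width was 181, 190 and 212 bp in the stronger 50%, 250, 257 and 302 bp with 500 bp, and 154, 163 and 190 bp with 3 kb. The cause was not tested.

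In the stronger 50% of each list, 70.4% of Caki-1 replicate 1 peaks were shared with replicate 2 and 63.6% the reverse. 786-O peaks were shared at 49.9% with replicate 1 and 52.1% with replicate 2, and the peaks of those replicates with 786-O at 53.4% and 50.3%. With a reciprocal overlap of 50%, which asks for more by construction, the 6 values in the same order were 52.7%, 47.2%, 33.1%, 34.9%, 34.2% and 32.3%. With the same number of peaks, the replicates shared 64.0% and 63.4%, 786-O shared 45.6% and 47.0% with them, and replicate 2 shared 46.7% with 786-O. The Jaccard difference between the replicates and the lines was 14.3 percentage points in the stronger 50% and 14.3 with the same number of peaks. The cause was not tested.

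Genes specific to 786-O numbered 851 with a window of 3 kb, 803 with no guard distance, and between 695 and 880 when a Caki-1 library was left out, which asks for absence from fewer libraries. Those specific to Caki-1 numbered 1405 with no guard distance. With 3 kb, 653 genes of replicate 1 were absent from replicate 2 and 1113 the reverse, and 1484 and 1196 genes of 786-O were absent from replicates 1 and 2. With no guard distance these numbers were 741, 1250, 1358 and 1117, and 1832 and 2100 genes of replicates 1 and 2 were absent from 786-O. Without the guard the order of lines and replicates turned for 1 pair of shares: 6.60% of the 10530 genes of 786-O were absent from replicate 2 and 6.27% of the 11513 genes of replicate 2 from replicate 1, and 1117 and 1250 without it. In the stronger 50% of each list, 1034 genes of 786-O were absent from replicate 2 and 1006 of replicate 1 from 786-O, against 1047 of replicate 2 absent from replicate 1. A shorter guard lets more genes count as absent by construction.

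Random lists matched on the CpG density of promoters were not run, since no genome was used here, nor were start sites of single transcripts, since the table holds gene models only. No paired analysis was possible because the lines share only replicate number 2. The unknown read depth limits every absence of a peak: of the weakest 10% of 786-O peaks, only 12.6% were shared with Caki-1 replicate 1.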

Other observations

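The gene families of the first paragraph were chosen after the data were seen, as were the test of library depth and the interval of the median rank at genes specific to Caki-1. The tests of DNA copy number, calling threshold and chromosome dosage were fixed before the values they measure were computed.

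Some gene families outside the fixed lists lay far from the share of all protein-coding genes with a gene-end peak, and others near it. That share was 52.7% in 786-O and 55.1% and 57.6% in Caki-1 replicates 1 and 2. Of 392 olfactory receptor genes, 16, 10 and 13 had a gene-end peak in 786-O and Caki-1 replicates 1 and 2, and of 94 keratin-associated protein genes 6, 1 and 1 had one. Beta-defensins had 2, 2 and 1 of 39 genes and taste receptors 3, 1 and 1 of 28. By contrast, 66, 65 and 67 of 77 mitochondrial ribosomal protein genes and 35, 35 and 36 of 40 proteasome subunit genes had one. Zinc finger genes of the ZNF series had 317, 293 and 312 of 517, and solute carriers 189, 212 and 221 of 386. HOX genes had 25, 20 and 22 of 40, from 18, 16 and 17 distinct peaks, so some of these genes share a peak. Counted in all 3 libraries, ZNF genes, solute carriers and HOX genes lay inside the random range (percentiles 92.0, 10.1 and 11.8). In 786-O alone the ZNF genes lay above it (percentile 100). The clustered protocadherin genes had 3, 3 and 22 of 53, but 3 distinct peaks accounted for each number, since many of these gene models share an end and a single peak there counts for all of them.

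The lines differ by chromosome in their number of peaks, with chromosomes 14, 6 and 22 richer in 786-O and chromosome 13 richer in Caki-1. Library depth predicts a similar factor on every chromosome, but the SD of the log2 ratio between the lines was 16.2 times that between the Caki-1 replicates, which argues against depth as the cause. DNA copy number predicts that the summit signal at shared peaks shifts with the number of peaks, and the correlation across chromosomes was rho = 0.912. In 10 Mb bins with at least 20 shared peaks, the log2 ratio of summit signal lay between 0.45 and 0.76 all along chromosome 14, but it went from 0.46 at 0 to 10 Mb to -0.84 at 80 to 90 Mb on chromosome 17 and from 0.35 at 40 to 50 Mb to -0.79 at 50 to 60 Mb on chromosome 5, so not every difference spans a whole chromosome. No DNA library without the antibody was used here, so a regional difference in the mark itself, as a property of the lines, remains open and untested.

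Genes specific to a line may in part follow the same chromosome differences. Their ratio correlated with the ratio of peak shares across chromosomes at rho = 0.759, in the direction that chromosome dosage predicts. Both ratios come from the same peak lists, so a regional difference in the mark would give that direction too. The correlation does not single out dosage. Of the 473 genes specific to 786-O, 338 lay outside the 6 most different chromosomes, as did 652 of the 864 specific to Caki-1. Regions of the other chromosomes were shifted as well. The log2 ratio of summit signal was 0.75 at 50 to 60 Mb on chromosome 3, where RBM15B of 786-O lies. It was -0.82 at 220 to 230 Mb on chromosome 1, where NUP133 of Caki-1 lies. The 10 Mb bins of COPE and SEMA5A of 786-O had 0.69 and 0.19, and that of BHMT2 and DMGDH of Caki-1 had -0.78. The bins of SPMAP2L, GNPTAB and CCDC92 of Caki-1 had -0.07, -0.05 and -0.08. Those of BANK1 and PCBP3 of Caki-1 went the other way, with 0.18 and 0.09. Since regions outside the 6 chromosomes were shifted, the counts of 338 and 652 are not free of these differences. The calling threshold is a further candidate explanation. The peaks at genes specific to 786-O had a median percentile rank of 48.2, between the bounds of 33 and 50 set for and against it, and those specific to Caki-1 had 53.6 as the median of the lower of their ranks (95% order-statistic CI 50.1 to 53.6), barely above 50, while all genes with a gene-end peak had medians of 85.5 in 786-O and 79.4 in both Caki-1 libraries. Only 10 of the 473 and 47 of the 864 ranked in the strongest 10% of their lists, among them SEMA5A and SPMAP2L, and since gene-end peaks rank far above 50 in general, that bound was too low to exclude the threshold, which cannot be told apart from true absence without read depth or a replicate of 786-O.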
